A study of Rattus norvegicus with 4 samples.

How the data were processed

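Gene expression was measured with Affymetrix GeneChip arrays (array A of the rat genome U34 set), which carry short oligonucleotide probe sets for rat transcripts, in cortex on the side of an experimental stroke. The stroke was made by closing the middle cerebral artery for 2 h from inside the vessel in ovariectomised female rats that received estradiol or placebo, per the labels and the series design text. That text describes pools of RNA from 3 animals, with 2 independent pools and 6 animals per group. It names tissue taken at 6 and 24 h and in cortex and striatum on both sides. The 4 arrays analysed here are labelled as cortex on the stroke side, and their codes carry a 6, but no label states the time in words, so the values below are not tied to a time. From 5 µg of total RNA, biotin-labelled cRNA was made, and 10 µg of it was hybridised, per the series design text.

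The deposited table holds 1 linear intensity per probe set and array, with no value below 0. The authors' 4 columns have nearly equal means after trimming 2% at each end, between 150.18 and 150.20, so each array had been scaled to a common level before deposit. A scaling factor and a share of present calls between 30 and 55% are named among the quality checks, per the series design text. The program that made the values is not given in the sources used here, and detection calls were not used here. No original scanner values were analysed here.

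Of 8799 rows, 59 control probe sets were left out. Of the other 8740 probe sets, 7006 had 1 gene symbol in the platform annotation, 308 had several and 1426 had none. No gene was named from a probe set with several symbols. Gene identifiers of 6985 probe sets were found in a RefSeq gene table of assembly GRCr8, which changed 0 symbols. That table was used for names alone, and no coordinates are given, since the array's annotation names no genome build.

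Array medians lay within 0.056 of each other on the log2 scale, below the limit of 0.1 set beforehand, so values were used as deposited. Intensities were transformed as log2(value + 16), and probe sets whose mean over the 4 arrays was below the 40th percentile, an intensity of 37.5, were left out. This left 5244 probe sets. Fold changes are on this log2(value + 16) scale, which understates changes of dim probe sets. Differences between estradiol and placebo were tested with limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes with an intensity trend, two-sided, and a Benjamini-Hochberg adjusted p below 0.05 as threshold. The fit had 2 residual degrees of freedom and 5.63 prior degrees of freedom. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

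Background was read from 23 control probe sets for bacterial, yeast and mouse transcripts. The highest of them stood at 33.9 and 37.8 on the estradiol arrays and at 37.8 and 30.1 on the placebo arrays. A probe set at or below this level on both arrays of a group is called at background there. Its fold is then given as a lower bound, the mean log2 intensity of the brighter group against that of the dimmer group with each array raised to its own highest foreign control. A log2 fold change printed for such a probe set is the fitted value on the offset scale, not a measured fold. Background refers to a probe set, and other probe sets of the same gene can lie above it.

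Lists of genes and the rule for named genes were fixed before the data were examined. Named genes were Cartpt, Esr1 and Esr2, up to 12 genes per direction, and the 2 highest and 2 lowest log2 fold changes in each list. The 12 per direction were to be genes past the adjusted threshold. Failing that, they were genes with an unadjusted p below 0.01 and both estradiol arrays on one side of both placebo arrays, in order of log2 fold change, each by its probe set of smallest p. There were 13 candidates in each direction. The rule's list members are named below where they bear on a comparison, and members named outside it were chosen after their values were seen.

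The 22 lists covered estradiol-related genes, neuropeptides and their processing, immediate early genes, heat shock and chaperones, inflammation, apoptosis, growth factors and receptors, glutamate receptors and transporters, GABA signalling, ion channels, antioxidant and metal binding, glycolysis and hypoxia, and oxidative phosphorylation. They also covered markers of neurons, astrocytes, microglia and macrophages, neutrophils, oligodendrocytes, vascular cells, blood cells, choroid plexus and meninges, and striatum. Each gene was represented by its probe set of highest mean, which gave 3181 genes, 394 of them in at least 1 list. Lists were tested with limma camera, which sets a list against all other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 22 lists. Camera with an estimated correlation and limma fry were run as alternatives.

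The other alternatives were offsets of 1 and 64, no filter and a filter at the 60th percentile, quantile normalisation, median centring, eBayes without a trend, the pool number as a block, the mean of a gene's probe sets, and each array left out in turn. With 1 array left in a group, the fit assumes that it varies like the other group. Lists without some members were added after the data were seen.

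The procedure was tested on simulated data for the 8740 probe sets, of which a median of 5244 passed the filter per run. In each of 20 runs, 200 probe sets that pass the filter in the data were changed. The procedure recovered 14.2% of changes of 1 on the log2 scale, 79.0% of changes of 2 and 95.9% of changes of 3, and 5.44% of its calls were false. The 200 held these sizes in nearly equal number, and many large changes loosen the Benjamini-Hochberg cut-off for the others. The data gave 0 calls and so a stricter cut-off, and these shares do not give the power of the comparison. In 100 simulated runs without a change, 0.02 lists were called per run on average. At its observed mean shift, given equally to each gene, the striatum list was called in 100% of simulated runs with the preset correlation. With an estimated correlation it was called in 0%, so that setting had no power for such an even shift. Simulated genes varied independently, so these values do not cover lists whose genes vary together between pools. The correlation estimated from the data was 0.32 for vascular, 0.52 for neuron and 0.42 for oligodendrocyte markers, against 0.047 for striatum and -0.043 for blood cell markers. The number of arrays limits the precision of every value.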

Results

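Expression was compared between the ischaemic cortex of ovariectomised rats given estradiol and that of rats given placebo. The question was which transcripts differ with estradiol replacement after a transient stroke. Each group had 2 arrays, and each array carried the pooled RNA of 3 animals. Pools are called estradiol 1 and 2 and placebo 1 and 2. Errors are the SD over the 2 pools of a group, and SE denotes the standard error of the limma fit.

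The arrays had median intensities of 57.2, 57.8, 55.0 and 56.8 in estradiol 1, estradiol 2, placebo 1 and placebo 2. Between 58.9 and 64.6% of probe sets lay above the brightest foreign control of their array. The 3' to 5' ratio of control probe sets, a measure of RNA integrity and labelling, lay between 1.30 and 1.45 for GAPDH, 1.28 and 1.58 for actin and 3.08 and 4.35 for hexokinase. Pools of the same group were no closer to each other than pools of different groups. The SD of the log2 difference over probe sets was 0.489 between the estradiol pools and 0.523 between the placebo pools, against 0.461 to 0.505 between estradiol and placebo pools.

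Among the genes with higher values under estradiol were 3 neuropeptide precursors. Tac1, which encodes the precursor of substance P, had an intensity of 394.5 ± 19.7 (SD, n = 2) with estradiol and 112 ± 5.44 (SD, n = 2) with placebo, a log2 fold change of 1.68 ± 0.21 (SE). Its other tested probe set gave 1.57. Penk, the enkephalin precursor, had 583 ± 81.2 against 227 ± 74.0, a log2 fold change of 1.33 ± 0.26 (SE). Cartpt, the precursor of cocaine- and amphetamine-regulated transcript peptide, had 81.6 ± 4.38 against 17.95 ± 5.16, a log2 fold change of 1.53 ± 0.34 (SE). Both placebo values of Cartpt lay within the background, so its level was at least 2.42-fold higher with estradiol, and its log2 fold change was 0.83 with an offset of 64. The filter at the 60th percentile removed its probe set. Cartpt had been singled out by the study from arrays of this kind, so its value here is not independent evidence.

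None of these differences passed the adjusted threshold. With limma and Benjamini-Hochberg adjustment, 0 of 5244 probe sets were called higher and 0 lower. The smallest adjusted p in limma was 0.285, for Tac1, and that of Cartpt was 0.998. At an unadjusted p below 0.05 there were 91 probe sets with higher and 70 with lower values under estradiol, 3.07% of those tested, and after median centring these were 71 and 90. Both estradiol pools lay on one side of both placebo pools for 1559 probe sets, or 29.7%, where chance gives 33.3%. For a single gene, the smallest two-sided exact permutation p that 2 against 2 pools allow is 0.333.

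Among the 12 genes named as higher was Dnmt1, the maintenance DNA methyltransferase, with a fitted log2 fold change of 2.04 ± 0.33 (SE). Its placebo values were at background, so this probe set was at least 3.08-fold higher with estradiol, and its other tested probe set gave 0.63. That other probe set stood at 112.6 and 100 with estradiol and at 36.2 and 104 with placebo, so its value rested on placebo 1. Cited2, a transcriptional coregulator, had 286 ± 119 (SD, n = 2) against 118 ± 9.05, a log2 fold change of 1.12, and 0.71 in its other tested probe set. Without estradiol 1 its value was also 0.71. For A2m, the acute-phase protease inhibitor alpha-2-macroglobulin, the named probe set gave 1.27, whereas the others gave 0.70, -0.15 and -0.21. The remaining genes were Cyp4f1 with 1.36, Nudt4 with 1.06, Ptpn23 with 1.02, Edn3, an endothelin, with 1.01, Mtarc2 with 0.91 and Tmem47 with 0.85. The named probe set was at background in both placebo pools for 4 of the 12, Dnmt1, Cartpt, Cyp4f1 and A2m, with bounds of at least 1.92-fold for Cyp4f1 and 2.54-fold for A2m. Other probe sets of A2m stood at 252 and 221 and at 358 and 346 with placebo.

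The 12 genes named as lower had fitted log2 fold changes from -1.83 to -0.86. Rhox5, a homeobox gene, had -1.83, the subunit gene of cytochrome c oxidase Cox6c -1.57, the olfactory receptor gene Or5a3 -1.48, Ccnd1, which encodes cyclin D1, -1.31, and Vhl, which targets hypoxia-inducible factors for degradation, -1.27. The named probe sets of these 5 genes were at background in both estradiol pools, so their values are bounds, at least 2.18-fold lower for Rhox5, 3.29-fold for Cox6c, 1.83-fold for Or5a3, 1.86-fold for Ccnd1 and 2.59-fold for Vhl. Other probe sets of Rhox5, Cox6c, Ccnd1 and Vhl were above background with estradiol, at 240.9 and 143 for Cox6c and 239.5 and 279 for Vhl. The others were Furin with -1.26, Vtn with -1.24, Rps24 with -1.18, Grid1 with -1.17, Apc and Lzts1 with -0.91 each, and Pcolce with -0.86. Probe sets of one gene often differed. Of the 24 named genes, 12 had other tested probe sets, and in 3 of these, Tac1, Dnmt1 and Cited2, all of them shared the sign with a log2 fold change above 0.5. For Dnmt1 this rested on placebo 1 alone. In 4 genes, A2m, Cox6c, Vhl and Apc, at least 1 other probe set had the opposite sign. The brighter Cox6c probe set gave 0.38. Other tested probe sets gave -0.15, -0.11 and -0.0047 for Ccnd1, -0.12 for Furin and -0.26 for Rhox5, all smaller falls than in the named ones.

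**Figure D1:**
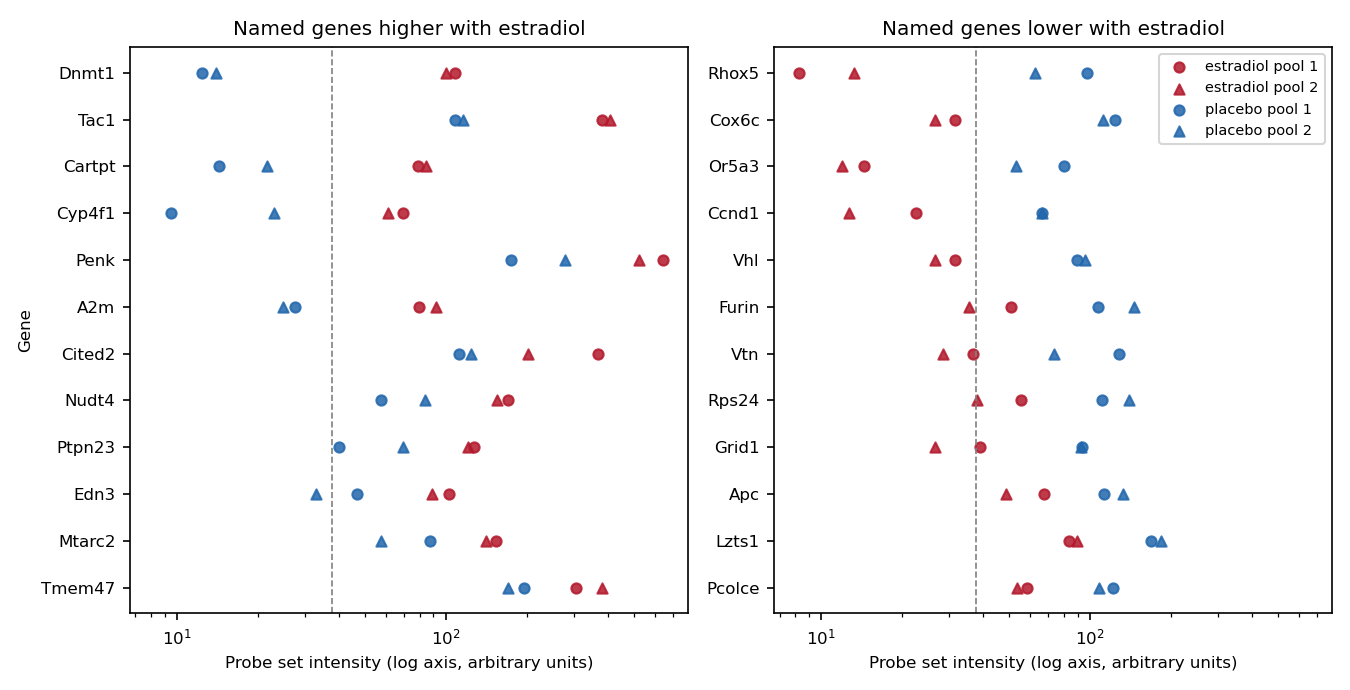
Intensity of the named genes on each of the 4 arrays, on a log axis in arbitrary units, with genes higher with estradiol on the left and lower on the right. Red marks are estradiol pools, blue marks placebo pools, circles pool 1 and triangles pool 2, and the dashed line is the highest foreign control on any array, 37.8. Cartpt stood at 78.5 and 84.7 with estradiol and at 14.3 and 21.6 with placebo, left of the line.

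Of the estrogen receptors, Esr1 could not be compared, and 1 probe set of Esr2 did not differ between groups beyond the spread between pools. Esr1 stood at background on every array, at 10.1, 11.3, 11.5 and 7.30, and was not tested. Esr2 had 95.0 ± 4.03 (SD, n = 2) with estradiol and 96.1 ± 29.8 with placebo, a log2 fold change of 0.01 ± 0.27 (SE), with a negative sign after quantile normalisation and median centring. Its other probe set stood at background on every array, at 5.4 and 7.9 with estradiol and 2.3 and 12 with placebo, and was not tested. Of 20 measured estradiol-related genes, 9 had values above 0 and 11 below, and the mean was 0.10 and the median -0.10. With 1 array left out, the mean lay between 0.041 (without placebo 2) and 0.17 (without placebo 1). In limma camera the list had an adjusted p of 0.882. Its genes with the highest values were Cartpt and Penk, which it shares with the neuropeptide list. Adjusted over the list alone in limma, 2 genes passed, Cartpt and Penk, against 0 over all probe sets. Cartpt was listed knowing that it had been singled out from arrays of this kind, so its pass is not independent evidence.

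Striatum markers lay higher with estradiol as a set, although the samples are labelled as cortex. Of 14 measured genes, 11 had log2 fold changes above 0, with a mean of 0.44 and a median of 0.31. Beside Tac1 and Penk these included Rgs9, a regulator of G protein signalling, with 1.23 ± 0.62 (SE), the dopamine receptor gene Drd1 with 0.81 ± 0.32, Pde1b with 0.45 and Adcy5 with 0.31. Without estradiol 2 the value was 0.22 for Rgs9, 0.45 for Drd1 and 0.00 for Adcy5, and without placebo 1 it was 0.04 for Pde1b. Rgs9 stood at 24.3 and 146 in the estradiol pools and at 16.2 and 21.0 in the placebo pools. It lay within the background in estradiol 1 as well as with placebo, so its value came from estradiol 2 alone and no bound is given. Chat, the acetylcholine-synthesising enzyme, had -0.44 (-0.14 without placebo 2), Pdyn -0.16 and Adora2a -0.03, and the last 2 turned in sign with an array left out. The list's adjusted p in limma camera was 9.81e-04 with the preset correlation, and the adjusted p was 0.833 with an estimated correlation. Adjusted over the list alone, 2 genes passed in limma, Tac1 and Penk. Without Tac1, Penk and Pdyn, which the neuropeptide list shares, the mean of the remaining 11 genes was 0.31 and the adjusted p in limma camera was 0.0654.

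The neuropeptide list, with 23 measured genes, did not pass as a set. Its mean was 0.28 and its median 0.02, with 12 genes above 0 and 11 below (limma camera, adjusted p = 0.124). It passed with the mean of each gene's probe sets (adjusted p = 0.0270) and without placebo 2 (0.0227). Adjusted over the list alone in limma, 3 genes passed, Tac1, Penk and Cartpt. The pass of Cartpt is again not independent evidence. Oxt, the oxytocin precursor, had 1.67 from estradiol 2 alone, with 493.5 against 41.9 in estradiol 1 and 32.1 and 44.3 with placebo. Cck, the cholecystokinin precursor, had 1309 ± 42.9 (SD, n = 2) with estradiol and 1931 ± 107 with placebo, a log2 fold change of -0.55 ± 0.18 (SE) that did not pass.

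Blood cell markers lay lower with estradiol as a set, with 6 of 9 measured genes below 0, a mean of -0.35 and a median of -0.41. Globin genes had the lowest values, with Hbb at 1634 ± 955 (SD, n = 2) with estradiol and 3286 ± 327 with placebo, a log2 fold change of -1.13 ± 0.37 (SE). Hbb-b1 had -0.92 and Hba-a3 -0.88, and the platelet gene Pf4 had -0.55. The globin values rested in part on estradiol 1, without which they were -0.50 for Hbb, -0.30 for Hbb-b1 and -0.47 for Hba-a3. Another globin gene of the list, Hbe1, had 0.26 (0.10 without estradiol 1), at intensities of 52.0 and 38.1 with estradiol and 32.1 and 37.1 with placebo. Cd4, an immune cell gene of the list, had 0.68 (0.11 without placebo 1). The adjusted p in limma camera was 0.0101, and the adjusted p was 0.833 with an estimated correlation. The list no longer passed with Hbb as its only globin (adjusted p = 0.0967 in limma camera), without estradiol 1 (0.101), without placebo 2 (0.0580) or without the intensity filter (0.192). Its mean was -0.20 without estradiol 1, -0.18 without the intensity filter and -0.69 with the filter at the 60th percentile.

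Vascular cell markers also lay lower as a set, with 13 of 16 genes below 0 and a mean of -0.21. Ocln, a tight junction gene, had -0.83 ± 0.30 (SE) and the transporter gene Slco1a4 of brain endothelium -0.53 ± 0.22. The adjusted p in limma camera was 0.0149, and the adjusted p was 0.983 with an estimated correlation. This shift rested on placebo 1, without which the mean was 0.04. It no longer passed without estradiol 1 (adjusted p = 0.101 in limma camera), without estradiol 2 (0.0675), without the intensity filter (0.0931) or with the filter at the 60th percentile (0.0552). That pool differed from placebo 2 in choroid plexus and meninges markers. Ttr, the abundant transthyretin transcript of choroid plexus, stood at 165 and 4312 in estradiol 1 and 2 and at 8034 and 74.3 in placebo 1 and 2. The 8 genes of that list had a mean of -0.02 and a median of 0.10 between treatments (limma camera, adjusted p = 0.903), and passed as higher without placebo 1 (mean 0.73, adjusted p = 0.00772) and as lower without placebo 2 (mean -0.77, 0.00154).

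**Figure D2:**
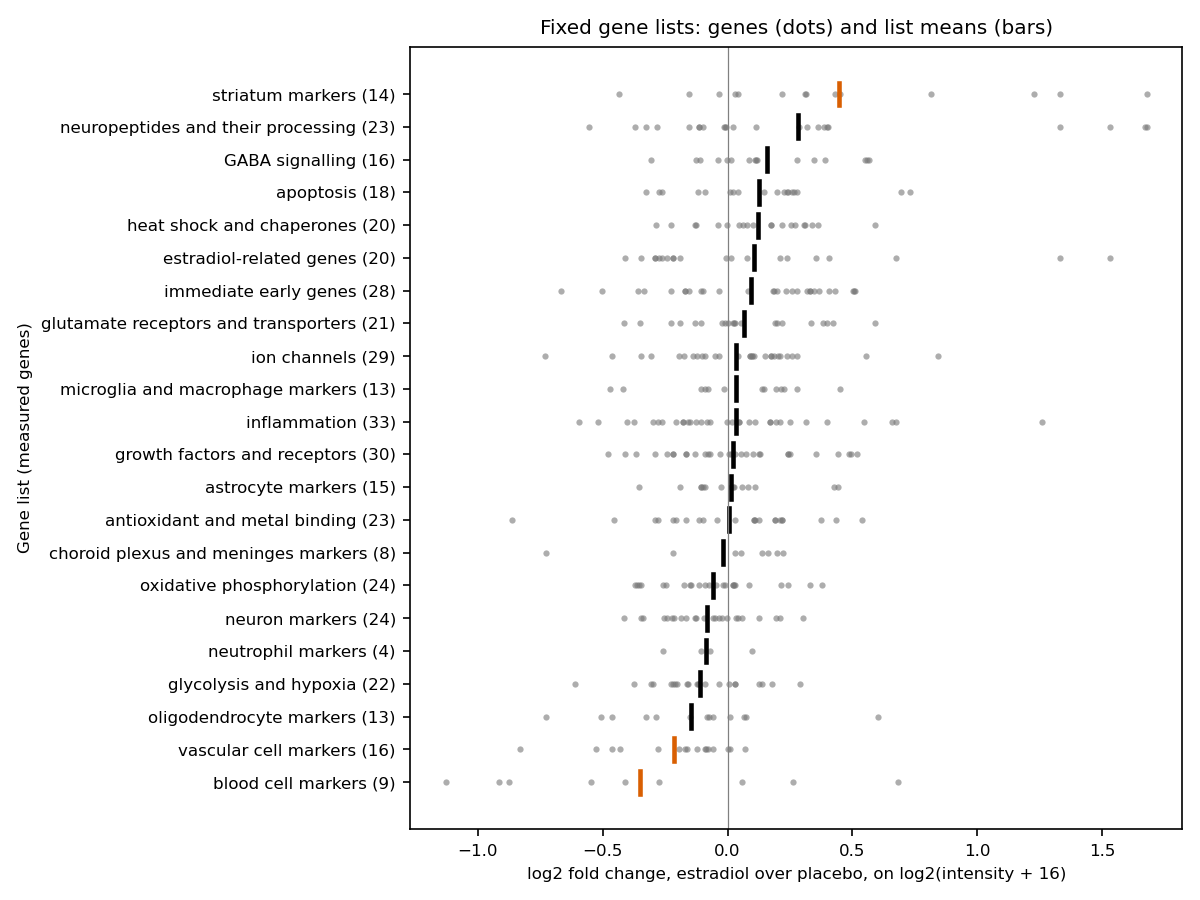
Log2 fold changes of estradiol over placebo for the measured genes of the 22 lists, on the log2(intensity + 16) scale, with the number of genes in parentheses. Grey dots are genes, bars are list means, and orange bars mark the 3 lists with an adjusted p below 0.05 in limma camera with the preset correlation, striatum (mean 0.44), vascular (-0.21) and blood cell markers (-0.35).

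Genes of the acute injury response did not pass as sets with all 4 arrays. Of 28 immediate early genes, 17 had values above 0 and 11 below, with a mean of 0.09 (limma camera, adjusted p = 0.720). Fos had 0.43, Junb 0.51 and Nr4a1 0.51, while Ier5 had -0.67 and Crem -0.50. Single pools decided these values. Without estradiol 1 they were -0.40 for Fos, -0.24 for Junb and -0.51 for Nr4a1, and without placebo 2 -0.34, -0.32 and -0.69. Ier5 had 0.22 without estradiol 2, and Crem -0.04 without placebo 1. The pools of each group differed more than the groups. Egr1, Nr4a1 and other members were brighter in pool 1 of both treatments, and the mean difference between pools 1 and 2 was 0.71 with estradiol and 0.75 with placebo. The list passed as higher without placebo 1 (mean 0.47, adjusted p = 1.80e-05 in limma camera) and without estradiol 2 (mean 0.45, 7.38e-04), and as lower without placebo 2 (mean -0.28, 0.00304).

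Inflammation genes numbered 33, with 16 above 0 and 17 below, a mean of 0.04, a median of -0.0015 and a test direction opposite to the mean (limma camera, adjusted p = 0.924). Nos2, the inducible nitric oxide synthase gene, had 163 ± 42.9 (SD, n = 2) with estradiol and 63.9 ± 43.3 with placebo, a log2 fold change of 1.26 ± 0.40 (SE), or 0.68 without placebo 1. The list passed as higher without placebo 1 (mean 0.30, adjusted p = 0.00121 in limma camera) and as lower without placebo 2 (mean -0.23, 0.00154). Heat shock and chaperone genes had 14 of 20 above 0, with a mean of 0.12 (adjusted p = 0.166 in limma camera), and Hspa5, an endoplasmic reticulum chaperone gene, had 0.59 (0.20 without placebo 2). That list passed as higher without placebo 1 (adjusted p = 0.00228). Apoptosis genes had 13 of 18 above 0, with a mean of 0.13 (adjusted p = 0.483), led by the stress transcription factor gene Ddit3 with 0.73 and Aifm1 with 0.69. Without estradiol 2 these were 0.38 and 0.24. Antioxidant and metal-binding genes had a mean of 0.01 (adjusted p = 0.948), with Prdx6 at 0.54 and Sod3 at -0.86 (-0.19 without placebo 1). They passed as higher without placebo 1 (adjusted p = 0.0239) and as lower without placebo 2 (0.0355). The test direction and the mean also differed in sign for growth factors and receptors, whose 30 genes had a mean of 0.02 (adjusted p = 0.882).

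Lists of energy metabolism and neurotransmission did not pass in limma camera with all 4 arrays. The mean was -0.11 for 22 glycolysis and hypoxia genes (adjusted p = 0.124) and -0.06 for 24 oxidative phosphorylation genes (adjusted p = 0.186). Slc16a1, a monocarboxylate transporter gene, had -0.61 (-0.39 without estradiol 1). The list mean was 0.16 for 16 genes of GABA signalling (adjusted p = 0.238), where Gad1, a GABA-synthesising enzyme gene, had 0.57 (0.03 without placebo 1). That mean was 0.07 for 21 glutamate receptor and transporter genes (adjusted p = 0.739) and 0.04 for 29 ion channel genes (adjusted p = 0.882), among which Cacnb2 had 0.84 (0.54 without placebo 1). With 1 array left out, ion channel genes passed as lower without placebo 1 (adjusted p = 0.0139 in limma camera) and as higher without placebo 2 (0.00304). Glycolysis and hypoxia genes passed as lower without estradiol 2 (0.0225), and genes of GABA signalling as higher without placebo 2 (0.00249).

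Markers of the main brain cell types gave no call in limma camera with all 4 arrays. Neuron markers had 17 of 24 genes below 0 and a mean of -0.08 (adjusted p = 0.141), and oligodendrocyte markers had 9 of 13 below 0 and a mean of -0.15 (adjusted p = 0.159). The mean was 0.01 for 15 astrocyte markers, with the opposite sign in the test (adjusted p = 0.882), 0.04 for 13 microglia and macrophage markers (adjusted p = 0.882) and -0.08 for 4 neutrophil markers (adjusted p = 0.739). Neuron markers passed as lower without placebo 1 (mean -0.29, adjusted p = 1.80e-05 in limma camera), and oligodendrocyte markers as lower without placebo 2 (mean -0.45, 1.67e-05). Mbp, the myelin basic protein gene, stood at 9112 and 7301 in the estradiol pools and at 12087 and 8178 in the placebo pools. In all, 3 of 22 lists passed with the preset correlation, and 0 passed with an estimated correlation or in limma fry. In simulated runs with independently varying genes, the striatum list was given the mean shift observed in these data. Camera then called it in 0% of runs with an estimated correlation and in 100% with the preset one. Genes that vary together between pools were not simulated, so the 100% does not speak for the preset correlation in these pools. The power of fry was not simulated. With the preset correlation, 1 list passed without estradiol 1, 4 without estradiol 2, 9 without placebo 1 and 10 without placebo 2.

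**Figure D3:**
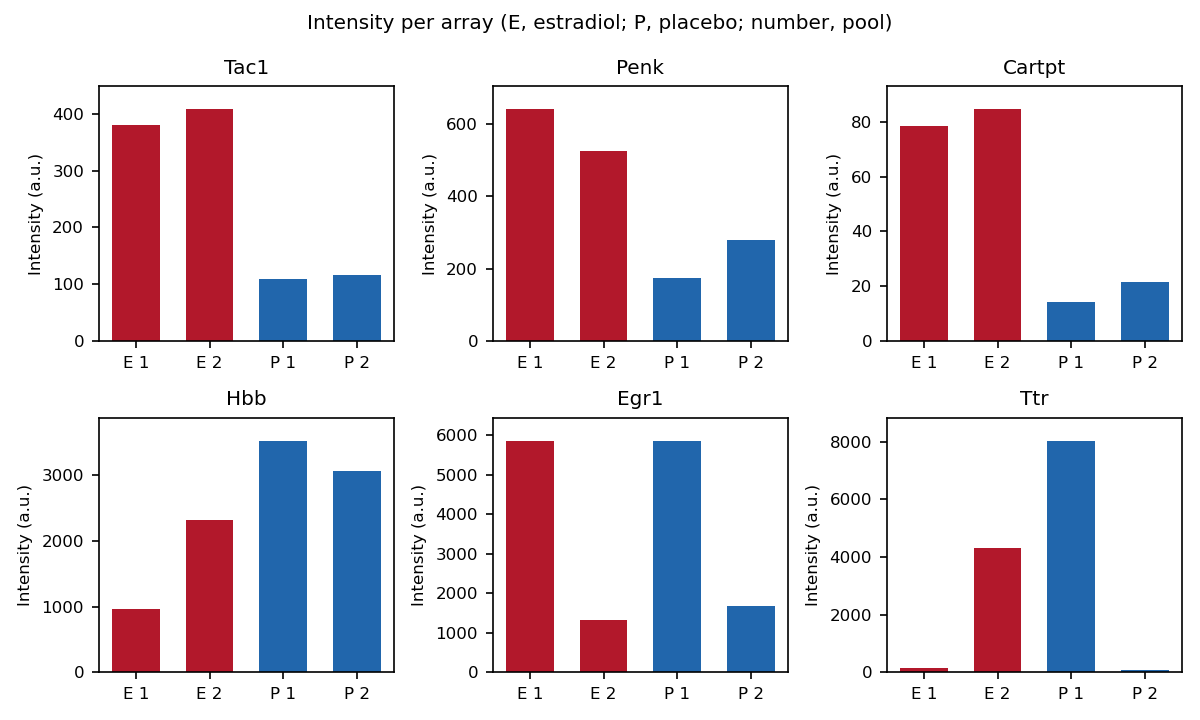
Intensity in arbitrary units of 6 genes on each array, with bars from 0, E for estradiol in red, P for placebo in blue and the number of the pool. Tac1, Penk and Cartpt were higher in both estradiol pools, Hbb was lower in both, Egr1 was brighter in pool 1 of each treatment, and Ttr stood at 8034 in placebo 1 and 4312 in estradiol 2.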

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

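The alternatives were set before the data were examined, except the lists without some members, which were chosen after the results were seen. The limma fit called 0 probe sets higher and 0 lower under every alternative run. At an unadjusted p below 0.05, there were 53 to 181 higher and 36 to 156 lower probe sets, the lowest with the filter at the 60th percentile and the highest without a filter, which test fewer and more probe sets. The higher ones numbered 59 without estradiol 2 and 145 without placebo 2. Cartpt had log2 fold changes from 0.83 with an offset of 64 to 2.15 with an offset of 1, and the filter at the 60th percentile removed it with 38 other named genes. Of 276 alternative values of the 24 genes named as higher or lower, 0 passed the adjusted threshold. Their direction was fixed by their selection, which required both estradiol pools on one side of both placebo pools, when an array was left out or the offset changed. Values close to background limit what dim genes such as Cartpt can show. The pool number as a replicate block gave 0 calls, 210 probe sets at an unadjusted p below 0.05, a smallest adjusted p of 0.765 in limma, a Cartpt log2 fold change of 1.53 and 3 lists, and it changed no call. Deviations of same-numbered pools had a correlation of 0.036 over probe sets, so the numbers were not taken to pair the pools.

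Lists called in limma camera numbered 3 and became 1 without a filter, 0 with an estimated correlation, 0 with fry and 1 with members left out of 3 lists, and 1 to 10 with an array left out. Striatum markers passed in every setting except an estimated correlation, fry and the list without its peptides. Of 333 list values, 36 turned in sign, and of 1341 values of 115 named genes, 42 did. The cause was not tested. With quantile normalisation, the sign turned in Esr2 (-0.010), Col3a1 (-0.018), growth factors and receptors (-0.0048) and choroid plexus and meninges markers (0.00036). With median centring, the sign turned in Esr2 (-0.021), Col3a1 (-0.022), growth factors and receptors (-0.013), antioxidant and metal binding (-0.028) and astrocyte markers (-0.019). With an offset of 64, the sign turned in Col3a1 (-0.00013). With the filter at the 60th percentile, the sign turned in estradiol-related genes (-0.0052), growth factors and receptors (-0.051) and antioxidant and metal binding (-0.0040). With no filter, the sign turned in antioxidant and metal binding (-0.0034), microglia and macrophage markers (-0.030) and choroid plexus and meninges markers (0.025). With the mean of a gene's probe sets, the sign turned in antioxidant and metal binding (-0.034) and choroid plexus and meninges markers (0.042). With an offset of 1, the sign turned in choroid plexus and meninges markers (0.020).

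Log2 fold changes with 1 array left out in turn turned in sign for these genes. Ranges were -0.26 to 0.29 for Esr2, -0.69 to 1.71 for Nr4a1, -0.32 to 1.33 for Junb, -1.55 to 0.22 for Ier5, -0.48 to 0.020 for Dnajb5 and -0.61 to 0.035 for Hyou1. They were -0.093 to 1.21 for Gabrb2, -0.70 to 0.44 for Gabrd, -0.11 to 0.71 for Nefm, -0.22 to 1.11 for Fabp7, -0.017 to 0.87 for Vim and -0.065 to 0.96 for Fcgr2b. There were also -0.89 to 0.058 for Lyz2, -0.96 to 0.021 for Ptprc, -0.52 to 0.71 for S100a8, -0.38 to 0.17 for Lcn2, -0.68 to 0.16 for S100a9 and -0.26 to 0.41 for Ugt8. The others were -1.84 to 0.39 for Enpp2, -0.31 to 0.34 for Col3a1, -0.27 to 0.71 for Slc5a5, -0.90 to 1.29 for Ptgds, -0.66 to 0.23 for Igfbp2, -0.52 to 0.21 for Pdyn, -0.40 to 1.26 for Fos and -0.27 to 0.20 for Adora2a. List means with 1 array left out were -0.28 to 0.47 for immediate early genes, -0.018 to 0.26 for heat shock and chaperones, -0.23 to 0.30 for inflammation, -0.00066 to 0.041 for growth factors and receptors and -0.016 to 0.15 for glutamate receptors and transporters. The means were -0.091 to 0.41 for GABA signalling, -0.22 to 0.29 for ion channels, -0.17 to 0.18 for antioxidant and metal binding, -0.29 to 0.13 for neuron markers and -0.074 to 0.10 for astrocyte markers. They were -0.074 to 0.14 for microglia and macrophage markers, -0.33 to 0.16 for neutrophil markers, -0.45 to 0.16 for oligodendrocyte markers, -0.47 to 0.041 for vascular cell markers and -0.77 to 0.73 for choroid plexus and meninges markers.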

Other observations

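The tests of blood content, of globins, of single estradiol pools, of array splits and of the differences between pools numbered 1 and 2 were chosen after the results were seen. The tests of non-peptide striatum markers and of other neuropeptide genes over all pools were set beforehand.

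The immediate early genes set apart pool 1 from pool 2 in both treatments. Of 28 measured genes, 18 were brighter in pool 1 in both groups, 6 of them more than 2-fold on the log2(intensity + 16) scale, and 1 was dimmer in both. Nr4a1 stood at 1557 and 365 in estradiol 1 and 2 and at 1233 and 220 in placebo 1 and 2. Fos stood at 1866, 578, 1326 and 443 in the same order, and Junb at 720, 246, 533 and 159. The difference was not particular to immediate early genes. Of the chaperone genes, Hspb1 stood at 2381, 1013.5, 2718 and 796 in that order, and Hspa1a at 4576, 2003, 4416 and 2489. The heat shock and chaperone list had a mean for pool 1 over pool 2 of 0.04 with estradiol and 0.28 with placebo. Oligodendrocyte markers differed between placebo pools, with a mean of 0.61 for pool 1 over pool 2, and by 0.07 between estradiol pools. Neuron markers had -0.41 and -0.07 in the same comparison, and ion channel genes -0.50 and -0.10.

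Several choroid plexus and meninges genes, Ttr, Igf2, Enpp2 and Ptgds, were brighter in estradiol 2 than in estradiol 1 and in placebo 1 than in placebo 2. Krt18 ran the other way, at 46.1 and 38.1 in the estradiol pools and 24.6 and 50.0 in the placebo pools. Kl was brighter and Slc5a5 dimmer in pool 1 of both treatments. Probe sets of Igfbp2 differed, and the one used for the list was brighter in pool 1 of both treatments, while A09811cds_s_at stood at 21.4 and 117 in the estradiol pools and at 320 and 29.3 in the placebo pools. Igf2 stood at 204 and 412.5 in the estradiol pools and at 510 and 156 in the placebo pools. The extracellular matrix gene Dcn, a member of the vascular list, stood at 22.1, 118, 153 and 19.8 in the same order.

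With 4 arrays, 3 splits into pairs exist, too few for a share below 0.05. In limma camera with the preset correlation, the treatment split called 3 lists and each other split called more. The highest, pool 1 against pool 2, called 8. That split also called 3 probe sets at an adjusted p below 0.05 in limma and had 381 at an unadjusted p below 0.05, against 0 and 161 for treatment. The split of estradiol 1 and placebo 2 from the others called 7 lists and 2 probe sets. Vascular markers passed in all 3 splits (limma camera, adjusted p = 0.0149 for treatment, 0.0112 for pool number and 0.0136 for the last). Their means were -0.21, 0.24 and -0.27. Striatum markers (0.348 for pool number and 0.996 for the last) and blood cell markers (0.373 and 0.845) passed for treatment alone. With an estimated correlation each of the 3 splits called 0 lists. That setting also called the striatum list in 0% of simulated runs at its observed shift, with genes varying independently.

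Tac1, Penk and Cartpt were higher with estradiol together with striatum markers, and striatal tissue in the estradiol pools may contribute, since the series also sampled striatum. Over both pools the 11 non-peptide striatum markers had a mean log2 fold change of 0.306 (95% bootstrap interval over genes 0.065 to 0.567). Of the list's 14 genes, 1 was at background in both placebo pools. Here and below, such intervals cover the spread over genes and not that between pools. Neuron markers had -0.412 (-0.537 to -0.299) between the placebo pools, an interval that excludes 0 without a treatment difference. The estradiol pools differed in the mean of these 11 genes, with 0.495 (0.158 to 0.927) in estradiol 2 and 0.117 (-0.080 to 0.290) in estradiol 1. In each pool 9 of the 11 lay above the placebo mean. Rgs9, bright in estradiol 2 alone, had 2.23 there and 0.22 in estradiol 1. Pdyn, left out as a peptide gene, stood at 687 in estradiol 2, against 1150 in estradiol 1 and 1066 and 923 with placebo. Tac1 and Penk together lay 2.75-fold above the placebo mean of intensity + 16 in estradiol 2 and 2.93-fold in estradiol 1. A rise of neuropeptide genes in general was left open by a mean of 0.109 (-0.078 to 0.336) over 19 other genes of the neuropeptide list. That mean leaned on Oxt, which had 1.67 from estradiol 2 alone. With Pdyn counted as well, the 20 genes had a median of -0.008. An effect of estradiol on Tac1, Penk and Cartpt also stays open, and striatal content cannot be told apart from it with 2 pools per group.

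Whether lower blood cell markers with estradiol reflect less blood in these pools stays open. The 5 members that are not globins, Alas2, Slc4a1, Pf4, Cd4 and Cd3g, had a mean log2 fold change of -0.098 (95% bootstrap interval -0.439 to 0.312). Pf4 (-0.55), Alas2 (-0.41) and Slc4a1 (-0.27) lay lower with estradiol, also with each array left out in turn. Cd4, at 0.68 (0.11 without placebo 1), and Cd3g lay higher. Whether the shift is one globin signal read by several probe sets stays open, since the list with Hbb as its only globin had a mean of -0.270 (95% bootstrap interval -0.696 to 0.189). Differences in residual blood between dissections and an effect of estradiol on vessels were not tested apart.

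Immediate early genes were higher in pool 1 than in pool 2 of both groups. The median log2 difference over all 5244 probe sets was -0.0247, so no uniform shift of the arrays accounts for this. The arrays had been scaled to a common level before deposit, which fixes such a median near 0. It cannot decide on differences between arrays that depend on intensity. A different severity or timing of the injury response is a possible explanation, and the inflammation list had 0.530 between placebo pools and 0.0967 between estradiol pools (95% bootstrap interval -0.036 to 0.227), which leaves it open. RNA quality was not settled by the log2 3' to 5' ratios and stays open. Hexokinase differed in opposite directions, by -0.410 between estradiol pools and by 0.239 between placebo pools. Its difference between treatments at one pool number reached 0.496. Actin differed by -0.306 and -0.077 between pools and by up to 0.125 between treatments. GAPDH differed little, by 0.080 and 0.031 between pools and by up to 0.122 between treatments. The design names no biological difference between pools 1 and 2, so no biological cause beyond severity or timing was weighed.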
